A study of Mus musculus with 24 samples.

How the data were processed

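Messenger RNA was selected with poly-T beads, fragmented and copied from random hexamers, per the labels' protocols. These name both a strand-keeping and a strand-free way to make the second strand and do not say which was used. The submitters' processing notes name fastp and HISAT2 2.0.5, which trim and align reads. The counter and the genome build are not given in the sources used here.

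One table for the whole series was deposited, with whole-number values per gene and annotation columns. Its 24 per-sample columns match no title or description of the 24 samples, so no test or comparison between groups was run. The columns also entered no computed result. No depth is given and no normalization was run, although depth per column would not need such a match. Column order and expression values were not used to assign columns. The tests planned before the data were examined, edgeR fits with their alternatives and gene list tests, were therefore not run.

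The count columns were inspected once to find their unit, which is how their values are known to be whole numbers and the first rows to hold large counts. All printed numbers about genes come from GENCODE, the fixed gene lists, a reference table of gene names and the annotation columns. These columns are identifier, symbol, chromosome, start, end, strand, length and biotype. The sources were read with Python 3.11.15 and pandas 2.3.3. Identifiers without version numbers were matched to GENCODE release M21, and positions were called the same only when chromosome, start, end and strand were all equal. Coordinates are printed as the table gives them, counted from 1. List genes were matched by symbol as written. The fixed panel and lists set which genes could be named, and only a few of them are named because no values go with them.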

Results

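The study profiled messenger RNA by sequencing in mouse bone marrow cells that the labels call sorted stromal cells, to ask what loss of HIF-2 in cells that express the leptin receptor changes after whole-body irradiation. HIF-2 is an oxygen-regulated transcription factor whose alpha subunit is encoded by Epas1. A Cre recombinase driven from the leptin receptor gene Lepr switched on the red fluorescent protein tdTomato, and red cells were sorted from the marrow of long bones. Control mice carried the Cre and the reporter only, and knockout mice also carried floxed HIF-2 alleles.

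The titles of the 24 samples placed 11 in the control genotype and 13 in the knockout. Of the control samples, 4 were unirradiated, 4 were collected 3 days after 4 Gy and 3 were collected 14 days after 4 Gy. Of the knockout samples, 7 were unirradiated, 3 were collected 3 days after 4 Gy and 3 were collected 14 days after 4 Gy. All unirradiated samples were labelled day 3, so the day 14 groups had no unirradiated group of their own day. For 1 sample, the unirradiated control replicate 4, the treatment field read as irradiated while the title read as unirradiated.

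No gene's expression was compared between these groups. The count columns carried the names A1 to A11 and B1 to B13, and none of the 24 names occurred in a sample title or description. The name B6 occurred in other label fields, where it is the mouse strain of all samples. The 11 A columns and 13 B columns equalled in number the control and knockout samples. By title, they equalled as well the 11 unirradiated and 13 irradiated samples, so that the letter did not identify genotype or dose. If the treatment field of unirradiated control replicate 4 is right instead, only the split by genotype still equals these numbers. No label tied a column to a dose, a day or a replicate. The effect of HIF-2 loss without irradiation is therefore not analysed here. Neither are the response to 4 Gy at day 3 and day 14 in each genotype and its difference between genotypes. The level of Epas1, which might bear on the genotype labels, is not analysed either.

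The gene annotation in the table belongs to no sample and could be read. It listed 54532 genes, of which 22046 were protein-coding, 9497 were processed pseudogenes and 5559 were long intergenic non-coding RNAs. Of these genes, 54495 had an identifier that GENCODE release M21, an annotation of mouse genome build GRCm38, also holds, and 53548 of those had the same chromosome, start, end and strand in both. These identical positions place the listed gene coordinates on build GRCm38, which the processing notes do not name. A total of 203 genes shared their symbol with another gene of the table.

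Epas1 (ENSMUSG00000024140) was listed on the plus strand of chromosome 17 from 86753907 to 86833410, with a start that differs from the 86753700 of release M21. Lepr (ENSMUSG00000057722), whose Cre allele marks the sorted cells, was listed on chromosome 4 from 101717404 to 101815352. Hif1a (ENSMUSG00000021109), which encodes the alpha subunit of HIF-1, was listed on chromosome 12 from 73901375 to 73947530. Cxcl12 (ENSMUSG00000061353), a chemokine that retains blood stem cells in the marrow, was listed on chromosome 6 from 117168535 to 117181367. Cdkn1a (ENSMUSG00000023067), a p53 target that arrests the cell cycle after DNA damage, was listed on chromosome 17 from 29090976 to 29100727. The coordinates of Lepr, Hif1a, Cxcl12 and Cdkn1a were the same in release M21.

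The genes chosen before the data were examined were 476 entries in 28 lists. The 15 lists of pathways and stromal functions held 337 entries, among them 25 HIF-responsive genes, 25 p53 target genes, 22 marrow stromal niche genes, 20 osteoblast and osteocyte genes and 20 adipocyte genes. The other 13 lists held 139 markers of cell types that a marrow sort could contain, among them 14 of neutrophils and 13 of monocytes and macrophages. By symbol, 474 entries were present in the table, and 26 of the 28 lists were present in full. Ccn2, a matricellular protein gene in the extracellular matrix list, was present under its older symbol Ctgf (ENSMUSG00000019997). The other incomplete list was that of erythroid markers, where Ahsp was not found. The table opened with Ngp and S100a9, genes known from neutrophils, which held large counts in every column when the table was inspected. Only the labels call the cells stromal. These large counts of neutrophil genes raise the question of sort purity but cannot answer it. Neither the depth of each column nor the counts of stromal and other marker genes were examined. The share of blood cells in the sorted samples was not analysed here. Presence in the table says only that a gene was annotated, and nothing about its expression.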

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

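Matching list entries by symbol or, through a reference table of gene names, by gene ID found 475 of 476 entries in place of 474, and 1 entry was found by neither route. This alternative was chosen after seeing the data, and the entry it added was Ccn2. The entry found by neither route was Ahsp, of the erythroid markers. No paired analysis was possible because the count columns carry no replicate number that the labels share. The alternatives planned for the group comparisons (normalization, low-count filter, other tests, blood marker covariate, smaller fits and leaving out each library) were not run, since no comparison was made.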
